A study of Homo sapiens with 12 samples.

How the data were processed

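RNA was measured by polyA-selected RNA sequencing in 12 libraries of MCF-7, an estrogen receptor positive human breast cancer cell line, carrying either a GFP control or HA-tagged EZH2, introduced stably with a lentivirus. EZH2 is the catalytic subunit of the Polycomb repressive complex PRC2, which lays down H3K27 methylation, a repressive histone mark. Cells were stripped of hormone for 3 days and then treated for 6 h with ethanol vehicle or 100 nM 4-hydroxytamoxifen (4-OHT), an active metabolite of tamoxifen that binds the estrogen receptor. The labels give 4 groups: GFP cells with vehicle (2 libraries), GFP cells with 4-OHT (4 libraries), EZH2 cells with vehicle (2 libraries) and EZH2 cells with 4-OHT (4 libraries). Groups and replicate numbers were taken from the labels. The labels do not say whether the replicates are separate cultures, or whether each construct was introduced more than once. P-values for single genes therefore measure the spread between these libraries, which may be technical. Those of the gene list tests (camera, below) set the listed genes against the other genes and do not measure agreement between libraries. The construct cannot be separated from the cell population that carries it.

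The deposited values are counts of reads per gene, with no normalization, as the authors made them. The submitters' processing notes name CASAVA, TopHat2 2.0.10, featureCounts and edgeR, with the genome build hg19, and per the file headers featureCounts 1.5.1 counted reads over the exons of the hg19 refGene annotation with its default settings. Those settings are unstranded and leave out reads that map to several places or to more than 1 gene. A gene's count may thus hold reads from the opposite strand, and the EZH2 count may or may not include transgene reads. The deposited table of the whole series held the same counts, with 0 differing values. The files list 27140 genes by symbol, and their coordinates give chromosome, start and end on hg19.

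Genes were filtered with edgeR's filterByExpr by group, which left 14477 genes, and counts were scaled by trimmed mean of M values (TMM). All 12 libraries were fitted together by group with edgeR 4.0.16 quasi-likelihood in R 4.3.3, which leaves 8 residual degrees of freedom, and each comparison was tested with a two-sided quasi-likelihood F test. P-values were adjusted by Benjamini-Hochberg over the genes tested, at a threshold of 0.05. The 5 comparisons were EZH2 against GFP with vehicle, EZH2 against GFP with 4-OHT, 4-OHT against vehicle in GFP cells, 4-OHT against vehicle in EZH2 cells, and the interaction, which is the 4-OHT effect in EZH2 cells minus that in GFP cells. Levels are TMM-scaled CPM (counts times 1e6 over the scaled library total), given as mean ± SD over the libraries of a group. Log2 fold changes are given ± an approximate SE, which is the size of the log2 fold change over the square root of its F statistic. Log2 CPM used a prior count of 2. For a gene with few counts in the lower group, the ratio of summed counts is given with an exact 95% interval, or against a floor of 3 counts over the group where the count was 0. These cover counting error only, since reads are not independent molecules.

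The comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Named are EZH2, GREB1 and ESR1, and for each comparison of groups the 8 genes with the largest rise and the 8 with the largest fall among genes past the threshold with a mean of at least 1 CPM in the higher group and no overlap of log2 CPM between the groups. For the interaction, up to 5 genes per direction were to be named. From each list described, 2 to 4 members with the smallest p are named. The 25 gene lists hold 693 symbols from textbook knowledge, of which 675 are in the files, and genes can be in several lists. They cover estrogen-induced genes, estrogen-repressed genes, PRC2 subunits, genes described as EZH2-repressed in cancer cells, developmental genes of the type that carries H3K27 methylation, mitosis, DNA replication, luminal epithelial genes, basal and mesenchymal genes, interferon-stimulated genes, MHC class I antigen presentation, p53 targets, the unfolded protein and integrated stress response, cholesterol synthesis and uptake, hypoxia and glycolysis, immediate early genes, NF-kB and inflammatory genes, the aryl hydrocarbon receptor (AhR) and xenobiotic response, growth factor receptors and adaptors, estrogen receptor (ER) cofactors, markers of fibroblasts, endothelium and leukocytes, cytosolic ribosomal proteins, the mitochondrial respiratory chain, mitochondrially encoded genes and replication-dependent histones. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 24 lists with tested members. They were tested again with the correlation estimated from the residuals. That form also rests on the 8 residual degrees of freedom, while the preset form draws on the number of genes. A call lost with an estimated correlation may thus reflect either change. The value given for a list is the mean log2 fold change of its members minus that of the other genes. The mitochondrially encoded list had 0 of its 15 symbols in the files and was not tested. The MHC class I list also holds CIITA, HLA-DRA, HLA-DRB1 and CD74, which belong to class II presentation.

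The fits were tested on simulated data with the libraries' own totals and each gene's own spread, in which genes varied independently of each other. Of 67 genes changed 2-fold, 42 were recovered for EZH2 against GFP with vehicle, 59 with 4-OHT, 48 for 4-OHT in GFP cells and 52 in EZH2 cells. At 1.5-fold, 8, 32, 16 and 17 of 67 were recovered, and false calls numbered 4 of 113, 9 of 166, 10 of 138 and 11 of 146 calls. A shift of -0.3 put into the DNA replication list was estimated at -0.31, with 0 other lists called.

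Alternatives in scaling and filtering were edgeR's RLE or upper-quartile factors, no filter, and a strict filter (at least 1 CPM in 4 libraries). Other tests were DESeq2 1.42.0, limma-voom and a test against a 1.2-fold minimum (glmTreat). For lists the other test was fry, which does not set a list against the other genes. Further alternatives were the libraries of a comparison alone and 4-OHT replicates 1 and 2 or 3 and 4 alone. The rest were replicate number as a block, the deposited series table, and leaving out each library in turn. Added after the data were seen were an offset that takes a spline trend (5 degrees of freedom) on GC content and gene length out of each library, the same offset without GFP vehicle replicate 2, counts thinned to the lowest total, the PRC2 list without EZH2, and list tests within pairs of 4-OHT replicates. GC content was that of the longest GENCODE transcript of each symbol and was found for 14028 of the tested genes (96.9%). With the offset, camera was run on log2 CPM with the trend taken out in place of the counts, because it cannot take offsets on counts. A list call that changes with the offset may thus reflect the other form of the test.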

Results

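The series asks how overexpressed EZH2 changes the transcriptome of MCF-7 cells. Gene counts were available for 12 libraries, 2 each of GFP and EZH2 cells with vehicle and 4 each with 4-OHT. Total counts ran from 16603514 (GFP vehicle replicate 2) to 28552965 (EZH2 4-OHT replicate 1), a ratio of 1.72. The common biological coefficient of variation was 0.135. Replicate counts were nowhere identical, and their chi-square per degree of freedom ran from 1.7 (EZH2 vehicle) to 83.7 (GFP vehicle). Among the GFP 4-OHT libraries it was 5.71 for replicates 1 and 2 and 2.4 for replicates 3 and 4, but 25.8 to 49.9 between these pairs.

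GFP vehicle replicate 2 lay apart from the other 11 libraries. It stood at -86.8 on the first principal component, which held 55.9% of the variance, where the others ran from -18.8 to 24.2. Ribosomal protein genes took 5.25% of its counts, against 2.57% to 3.59% in the others. The shortest 10% of genes had a median deviation of 0.695 (log2) from the mean of all libraries, and the longest 10% -0.554. A trend on GC content and gene length accounted for 51.7% of the variance of its deviations, against 6.26% to 32.9% in the others. For the comparisons that use it (EZH2 against GFP with vehicle, 4-OHT in GFP cells, and the interaction), the number of genes called is therefore given with and without it, a choice planned as 1 of the left-out libraries.

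**Figure D1:**
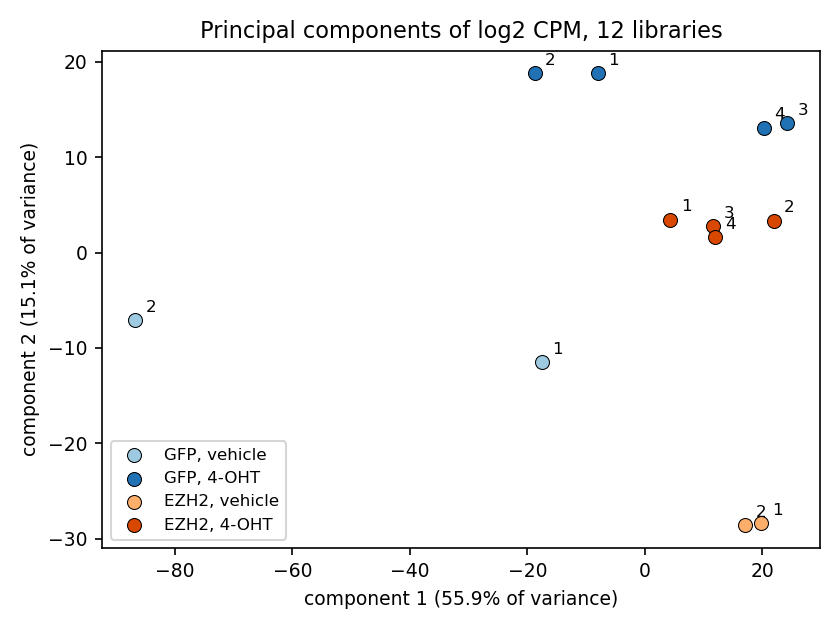
Principal components of log2 CPM in the 12 libraries (x axis, component 1 with 55.9% of the variance; y axis, component 2 with 15.1%), with 1 point per library, colours for the 4 groups and replicate numbers beside the points. GFP vehicle replicate 2 stands at -86.8 on component 1, and on component 2 the EZH2 vehicle libraries (-28.4 and -28.6) lie at one end and the GFP 4-OHT libraries (13.1 to 18.8) at the other.

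EZH2 (chromosome 7, 148504464 to 148581441, hg19) matched the labels in every library. It stood at 91.3 ± 0.505 CPM (SD, n = 2) in GFP cells with vehicle and 666 ± 0.556 CPM (n = 2) in EZH2 cells with vehicle, a log2 fold change of 2.87 ± 0.09 (adjusted p = 4e-09). With 4-OHT it stood at 94.5 ± 2.11 CPM (n = 4) and 584 ± 9.19 CPM (n = 4), a log2 fold change of 2.63 ± 0.06 (adjusted p = 1.4e-10). 4-OHT itself moved EZH2 by 0.05 ± 0.07 in GFP cells (adjusted p = 0.61) and by -0.19 ± 0.07 in EZH2 cells (adjusted p = 0.35). Fitted on the 4 vehicle libraries alone, the EZH2 difference was also 2.87 but did not pass the threshold (adjusted p = 0.11).

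**Figure D2:**
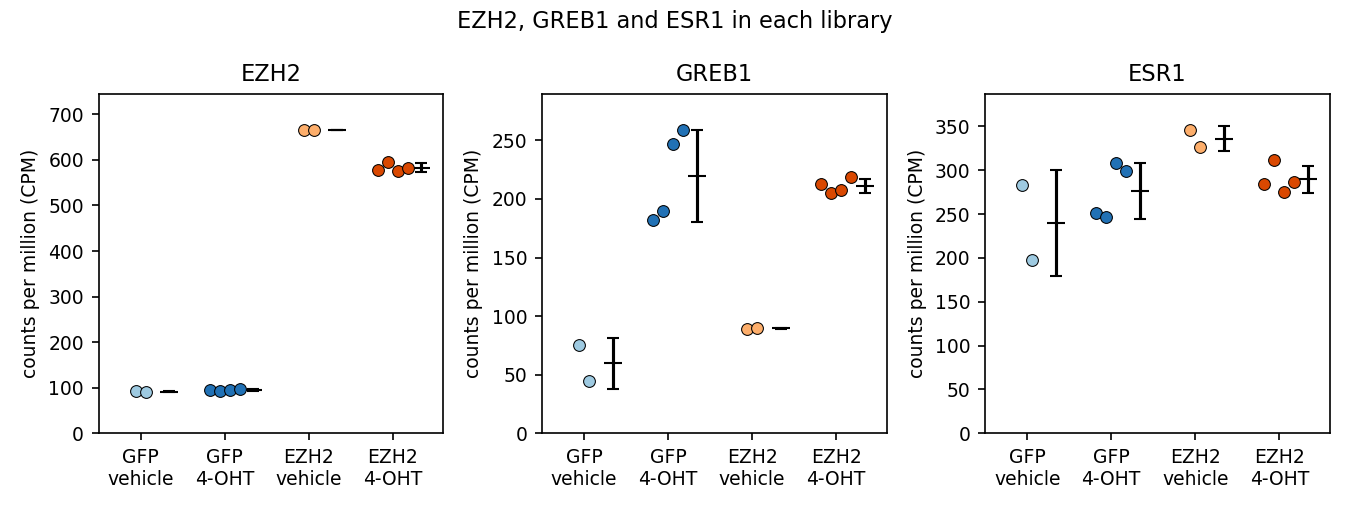
CPM (y axes, from 0) of EZH2, GREB1 and ESR1 in each library by group (x axes), with 1 point per library and a bar for mean ± SD of the group. EZH2 lies between 90.9 and 97.1 CPM in all 6 GFP libraries and between 575 and 666 CPM in all 6 EZH2 libraries, and GREB1 lies higher with 4-OHT than with vehicle in both cell populations.

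With vehicle, the comparison of EZH2 with GFP cells asks what EZH2 overexpression changed before the drug. Beside EZH2, the genes that rose and stayed past the threshold without GFP vehicle replicate 2 included CLEC3A, a C-type lectin (log2 fold change 2.37 ± 0.31), and FAM84A (2.22 ± 0.27). LST1, a leukocyte-specific transcript of the MHC region, fell from 4.11 ± 0.638 to 0.619 ± 0.0826 CPM (SD, n = 2 each), a log2 fold change of -2.7 ± 0.35. Without that library these were 1.86, 2.11 and -2.55 (adjusted p = 0.0059, 0.026 and 0.026). CLEC3A was 3.71 without GFP vehicle replicate 1. CLEC3A did not pass without EZH2 vehicle replicate 1 (adjusted p = 0.12), FAM84A without EZH2 vehicle replicate 2 (adjusted p = 0.061), and LST1 without either (adjusted p = 0.13 and 0.12). In all, 2358 genes rose and 2586 fell with all libraries, and 11 rose and 6 fell without GFP vehicle replicate 2. All 17 of these were among the former, with the same sign.

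The other large changes with vehicle lost their calls without GFP vehicle replicate 2 and without either EZH2 vehicle replicate. CD36, a fatty acid transporter, had 52 counts in EZH2 cells and 2 in GFP cells, a ratio of 22.5 with a 95% counting interval of 5.92 to 191. ZBED6 rose by 3.87 ± 1.01 and KIAA0754 by 2.34 ± 0.72 on the log2 scale, as did the noncoding NPTN-IT1 (2.99 ± 0.77) and RBM5-AS1 (2.63 ± 0.7). The falls were those of CACNG1, a muscle calcium channel subunit (-2.33 ± 0.44), the histone gene HIST1H4C (-2.27 ± 0.61), KRT18P55 (-1.95 ± 0.68), C1orf162 (-1.92 ± 0.53), C4orf48 (-1.75 ± 0.37), LTC4S, which encodes leukotriene C4 synthase (-1.75 ± 0.33), and CDC37L1-AS1 (-1.72 ± 0.54). Without GFP vehicle replicate 2 the log2 changes of these 12 genes were 1.91 to 3.69 for the rises and -1.87 to -0.89 for the falls, with adjusted p from 0.15 to 0.36. Without GFP vehicle replicate 1, NPTN-IT1 stood at 4.63, and CD36 had 0 counts left in GFP cells (fitted log2 fold change 7.69, which is no bound). HIST1H4C had 37 and 9 counts, a ratio of 4.76 (95% counting interval 2.25 to 11.2). Several of these (RBM5-AS1, NPTN-IT1, CDC37L1-AS1, ZBED6 and KIAA0754) lie antisense to or inside other genes, whose reads unstranded counting cannot separate, and KRT18P55 is a pseudogene.

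ESR1, which encodes the estrogen receptor (chromosome 6, 152011631 to 152450738), stood at 240 ± 60.9 CPM in GFP and 336 ± 14.8 CPM in EZH2 cells with vehicle (SD, n = 2 each). Its log2 difference of 0.48 ± 0.16 (adjusted p = 0.04) was 0.25 without GFP vehicle replicate 2 (adjusted p = 0.34), 0.75 without GFP vehicle replicate 1 (adjusted p = 0.00098), and -0.04 with the GC and length trend taken out (adjusted p = 0.73). It also did not pass without either EZH2 vehicle replicate (adjusted p = 0.16 and 0.12) or without EZH2 4-OHT replicate 1, 3 or 4 (adjusted p = 0.054 to 0.056). GREB1, an estrogen-induced ER cofactor (chromosome 2, 11674242 to 11782912), stood at 59.6 ± 21.7 and 89.6 ± 0.417 CPM, a log2 difference of 0.58 ± 0.22 that did not pass the threshold (adjusted p = 0.053) and was 0.26 without that library (adjusted p = 0.41).

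DNA replication genes were lower in EZH2 cells with vehicle. Of all genes tested, 34.2% were called in this comparison, the share against which the counts per list are to be read. Of 33 tested, 0 rose and 15 fell (0 and 17 adjusted over the list alone), among them the S-phase regulator E2F1 (-0.88 ± 0.16), CDC45 (-0.7 ± 0.13) and the helicase subunit MCM7 (-0.73 ± 0.14). As a list they lay at -0.32 relative to other genes (adjusted p = 0.00028), and at -0.32 without GFP vehicle replicate 2 (adjusted p = 6.9e-09), where 0 members passed, but did not pass with an estimated correlation (adjusted p = 0.29). Of 12 PRC2 subunit genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone), with JARID2 at 0.63 ± 0.19, MTF2 at 0.75 ± 0.22 and PHF19 at -0.67 ± 0.17. The PRC2 list lay at 0.52 (adjusted p = 0.00028, and adjusted p = 0.33 with an estimated correlation), at 0.31 without EZH2 itself (adjusted p = 0.15). With GFP vehicle replicate 2 left out only EZH2 passed, and these 2 values were 0.35 and 0.12. The list without EZH2 lay at 0.55 with GFP vehicle replicate 1 left out. The full list lay at 0.19 with the trend taken out (adjusted p = 0.54).

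With all libraries, neither genes described as EZH2-repressed nor estrogen-induced genes passed by camera with vehicle. Both passed with fry (adjusted p = 0.016 and 0.023), which does not set them against the other genes. Of all genes tested, 34.2% were called here. Of 18 genes described as EZH2-repressed, 4 rose and 1 fell (4 and 1 adjusted over the list alone), with the cell cycle inhibitor CDKN2B at 0.75 ± 0.15 and MSMB at -1.58 ± 0.4. Together the genes lay at 0.1 (adjusted p = 0.23), but passed at 0.15 with the GC and length trend taken out (adjusted p = 0.039). Of 34 estrogen-induced genes, 3 rose and 8 fell (5 and 8 adjusted over the list alone), with XBP1 at -0.48 ± 0.09, TFF3 at -1.54 ± 0.32 and TFF1 at -1.06 ± 0.24. The listed genes lay at -0.1 (adjusted p = 0.31), and at 0.05 and -0.11 these 2 lists did not pass without GFP vehicle replicate 2 (adjusted p = 0.13 and 0.085). The stimulus-induced immediate early genes lay at -0.28 (adjusted p = 0.043, and adjusted p = 0.4 with an estimated correlation), with 1 of 29 higher and 8 lower (1 and 7 adjusted over the list alone). NR4A1 stood at -0.84 ± 0.14 and FOS at -0.67 ± 0.14. The list lay at -0.11 with the trend taken out (adjusted p = 0.72), and it lost its call without GFP vehicle replicate 1 or EZH2 vehicle replicate 1. The genes of the MHC class I list, which also holds class II genes, lay at -0.36 (adjusted p = 0.028, and adjusted p = 0.4 with an estimated correlation). Of 18, 1 was higher and 8 lower (1 and 8 adjusted over the list alone), among them PSMB10 (-1.11 ± 0.27) and HLA-A (-0.6 ± 0.18). As a list they lay at -0.57 and -0.2 without GFP vehicle replicate 1 or 2.

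Ribosomal protein and respiratory chain genes were high in GFP vehicle replicate 2 and lower in EZH2 cells with vehicle. Of 51 ribosomal protein genes, 0 rose and 48 fell (0 and 49 adjusted over the list alone), with RPS28 at -1.24 ± 0.28 and RPL35 at -1.23 ± 0.28. Together the genes lay at -0.91 (adjusted p = 2.3e-17, but adjusted p = 0.4 with an estimated correlation), at -0.51 without that library, where 0 of them passed, and at -0.44 with the trend taken out. Of 36 respiratory chain genes, 0 rose and 28 fell (1 and 30 adjusted over the list alone), with COX6C at -1.17 ± 0.19 and COX7A2 at -1.02 ± 0.21. This list lay at -0.69 (adjusted p = 5.6e-10, but adjusted p = 0.4 with an estimated correlation), at -0.39 without that library and at -0.31 with the trend taken out.

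The quasi-likelihood test over all 12 libraries called 4944 of 14477 genes with vehicle, and of all members of the gene lists only EZH2 and FOS passed without GFP vehicle replicate 2. The count moved by over 1.5 times without GFP vehicle replicate 1 (8395 genes), GFP vehicle replicate 2 (17), EZH2 vehicle replicate 1 or 2 (7 each) and EZH2 4-OHT replicate 3 or 4 (3019 and 3108), and on the 4 vehicle libraries alone it was 0.

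With 4-OHT, where 4 libraries faced 4, the comparison of EZH2 with GFP cells asks what EZH2 changed in drug-treated cells, and none of its libraries was GFP vehicle replicate 2. It called 150 genes, 96 higher and 54 lower in EZH2 cells, while with the GC and length trend taken out 366 were higher and 473 lower. Beside EZH2, the largest rises were those of PIK3R5, a regulatory subunit of PI3-kinase gamma (0.172 ± 0.0578 to 1.18 ± 0.218 CPM, log2 fold change 2.7 ± 0.27), the zinc finger factor SALL2 (1.9 ± 0.293 to 7.79 ± 0.484 CPM, 2.02 ± 0.16), the oocyte protease ASTL (1.95 ± 0.3) and the calcium-binding NECAB1 (1.63 ± 0.25). CLEC3A (1.6 ± 0.2), ANKRD1, a target of the YAP coactivator (8.14 ± 0.686 to 23.2 ± 3 CPM, 1.51 ± 0.11), and CHST3, a chondroitin sulfotransferase (1.5 ± 0.24), followed. The largest falls were those of LST1 (2.16 ± 0.542 to 0.452 ± 0.208 CPM, -2.22 ± 0.28), LINC00052 (11.3 ± 0.184 to 3.57 ± 1.18 CPM, -1.65 ± 0.19), the monocarboxylate transporter SLC5A8 (9.08 ± 1.61 to 3.09 ± 0.545 CPM, -1.56 ± 0.19), the clock repressor BHLHE41 (-1.52 ± 0.2) and the channel family gene ANO3 (-1.51 ± 0.27). The lipid transporter ABCA12 (-1.3 ± 0.19), LOC101927523 (-1.25 ± 0.25) and LINC01132 (-1.24 ± 0.19) also fell. Adjusted p for these 16 genes ran up to 0.035, and each SD is over n = 4. CHST3 did not pass without GFP 4-OHT replicate 4 (adjusted p = 0.05, just above the threshold), ANO3 without any 1 of 6 libraries (adjusted p up to 0.081) and LOC101927523 without any 1 of 10 (adjusted p up to 0.13).

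DNA replication and mitosis genes were lower in EZH2 cells under 4-OHT. All 33 DNA replication genes had a negative log2 fold change. Of these, 0 rose and 1 fell (0 and 21 adjusted over the list alone), namely RRM2, a subunit of ribonucleotide reductase (-0.36 ± 0.07), while 10 fell without GFP vehicle replicate 2, and GINS3 stood at -0.4 ± 0.09 and CDC6 at -0.34 ± 0.08. The listed genes lay at -0.28 (adjusted p = 1.6e-19), and it passed with an estimated correlation as well (adjusted p = 0.0016). It lay at -0.25 on 4-OHT replicates 1 and 2 alone (adjusted p = 8.6e-07) and at -0.32 on replicates 3 and 4 alone (adjusted p = 3.9e-15). All 30 mitosis genes were negative too, but 0 were called (0 rose and 5 fell adjusted over the list alone), with the cyclins CCNB2 at -0.32 ± 0.08 and CCNB1 at -0.29 ± 0.08. That list lay at -0.24 (adjusted p = 8e-11, and adjusted p = 0.057 with an estimated correlation), at -0.16 on replicates 1 and 2 (adjusted p = 0.0038) and at -0.33 on replicates 3 and 4 (adjusted p = 2.5e-12).

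Immediate early, interferon-stimulated and respiratory chain genes passed as lists between constructs under 4-OHT at the preset correlation, but not with an estimated one. Of 29 immediate early genes, 1 rose and 4 fell (2 and 6 adjusted over the list alone), the 4 being the transcription factors NR4A1 (-0.56 ± 0.1), EGR3 (-1.15 ± 0.2), EGR1 (-0.61 ± 0.11) and FOS (-0.5 ± 0.1). The list lay at -0.19 (adjusted p = 0.00028, and adjusted p = 0.075 with an estimated correlation). Of 38 interferon-stimulated genes, 32 were negative and 0 called (0 and 2 adjusted over the list alone), with OASL at -0.45 ± 0.1 and IFIT2 at -0.49 ± 0.13. They lay at -0.13 (adjusted p = 0.0005, and adjusted p = 0.05, just above the threshold, with an estimated correlation). The estimate was 0.009, below the preset 0.01, so a higher correlation did not make this loss. Respiratory chain genes lay at -0.12 (adjusted p = 0.012, and adjusted p = 0.7 with an estimated correlation) with 0 of 36 called (0 adjusted over the list alone) and COX6C at -0.53 ± 0.13. They lay at -0.06 with the trend taken out (adjusted p = 0.15), at -0.25 on 4-OHT replicates 1 and 2 alone (adjusted p = 5.9e-05) and at 0.01 on replicates 3 and 4 alone (adjusted p = 0.99), and their call was lost without GFP 4-OHT replicate 1 or 2 (-0.07 and -0.05) or EZH2 4-OHT replicate 4. On the same pairs immediate early genes lay at -0.27 (adjusted p = 0.00064) and -0.13 (adjusted p = 0.094), and interferon-stimulated genes at -0.18 (adjusted p = 0.0046) and -0.09 (adjusted p = 0.051). Ribosomal protein genes lay at -0.09 with all libraries (adjusted p = 0.13, and adjusted p = 0.82 with the estimated correlation of 0.886), with 0 of 51 called (0 adjusted over the list alone). At the preset correlation they passed in opposite directions on the pairs, at -0.29 (adjusted p = 2.6e-07) and 0.14 (adjusted p = 0.032). More members fell without GFP vehicle replicate 2, namely 2 interferon-stimulated genes, 5 immediate early genes, and 1 gene each of the respiratory chain and mitosis lists.

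The estrogen-related and PRC2 lists moved little between constructs under 4-OHT. Of 34 estrogen-induced genes, 2 rose and 3 fell (5 and 4 adjusted over the list alone), with STC2 at 0.53 ± 0.06, PDZK1 at 1.05 ± 0.17 and XBP1 at -0.42 ± 0.07. As a list they lay at -0.06 (adjusted p = 0.53). GREB1 stood at 220 ± 39.3 CPM in GFP and 211 ± 6.16 CPM in EZH2 cells (SD, n = 4 each, log2 difference -0.06 ± 0.15, adjusted p = 1), and ESR1 at 276 ± 31.7 and 289 ± 15.9 CPM (0.07 ± 0.11, adjusted p = 0.99). Of 15 estrogen-repressed genes, 2 rose and 0 fell (3 and 0 adjusted over the list alone), namely BCAS1 (0.59 ± 0.08) and the xenobiotic enzyme CYP1A1 (0.51 ± 0.09). That list lay at 0.1 (adjusted p = 0.039, and adjusted p = 0.11 with an estimated correlation), and 5 of the 8 4-OHT libraries ended the call when left out (GFP replicates 1, 3 and 4, EZH2 replicates 1 and 4). It was also lost with the trend taken out (still at 0.1, adjusted p = 0.14, with the other form of the test) and on 4-OHT replicates 1 and 2 or 3 and 4 alone (adjusted p = 0.21 and 0.051). The PRC2 list lay at 0.2 (adjusted p = 1.2e-07, and adjusted p = 0.05, just above the threshold, with an estimated correlation) through EZH2, the only 1 of 12 members called (1 adjusted over the list alone). The call was lost with the trend taken out, where the value hardly moved (0.18, adjusted p = 0.44) but the form of the test changed as well. It was also lost on 4-OHT replicates 3 and 4 alone (0.09, adjusted p = 0.7). Without EZH2 the list lay at -0.02 (adjusted p = 0.49). Of 18 genes described as EZH2-repressed, 1 rose and 0 fell (3 and 2 adjusted over the list alone), namely DAB2IP, a Ras GTPase-activating protein (0.4 ± 0.09, adjusted p = 0.048), with CDKN2B at 0.49 ± 0.11 (adjusted p = 0.053). Together the genes lay at 0.01 (adjusted p = 0.29), and 2 rose without GFP vehicle replicate 2.

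DESeq2 called 364 genes for EZH2 against GFP with 4-OHT, the test against a 1.2-fold minimum 48, and the trend offset 839 (366 higher and 473 lower, and without GFP vehicle replicate 2 615 and 885). The count moved by over 1.5 times without GFP 4-OHT replicate 1, 3 or 4 (70, 75 and 70) and EZH2 4-OHT replicate 1, 3 or 4 (66, 61 and 58). It also moved by over 1.5 times without any 1 of the vehicle libraries. These are in neither group compared but enter the gene filter and the shared estimate of spread, and which of the 2 made the change was not tested. On 4-OHT replicates 1 and 2 alone 1 gene was called, and on replicates 3 and 4 alone 2.

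Between vehicle and 4-OHT, 66 genes rose in EZH2 cells under both, where 15.6 would be shared by chance, and 27 fell under both (9.65 by chance), with 0 called in opposite directions. Across all 14477 genes the log2 fold changes of EZH2 against GFP under vehicle and 4-OHT had a Pearson r of 0.38 and a Spearman rho of 0.37 across genes, which are not independent replicates. The Pearson r was 0.25, 0.14, 0.53 and 0.51 without GFP 4-OHT replicates 1 to 4, 0.45 without GFP vehicle replicate 2, and 0.7 on 4-OHT replicates 1 and 2 alone. Without GFP vehicle replicate 2, 10 of the 11 genes that rose and all 6 that fell with vehicle were also called with 4-OHT.

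In GFP cells, 4-OHT raised estrogen-induced genes. GREB1 rose from 59.6 ± 21.7 CPM (SD, n = 2) to 220 ± 39.3 CPM (n = 4), a log2 fold change of 1.88 ± 0.2 (adjusted p = 0.00018), and by 1.55 without GFP vehicle replicate 2 (adjusted p = 0.00031). Of 34 estrogen-induced genes, 25 rose and 1 fell (28 and 3 adjusted over the list alone), among them RAPGEFL1 (2.36 ± 0.11), the glycoprotein hormone gene STC2 (1.4 ± 0.08), the adenosine receptor ADORA1 (2.13 ± 0.16) and the keratin KRT13 (6.1 ± 0.42). The listed genes lay at 1.1 (adjusted p = 2.5e-39, and adjusted p = 1.9e-05 with an estimated correlation), and at 1.1 without GFP vehicle replicate 2, where 21 rose and 0 fell. Of 15 estrogen-repressed genes, 0 rose and 9 fell (0 and 9 adjusted over the list alone), among them the proapoptotic BMF (-0.96 ± 0.09), YPEL3 (-1.27 ± 0.18) and CYP1A1 (-0.55 ± 0.11). The list lay at -0.53 (adjusted p = 9.1e-06, and adjusted p = 0.011 with an estimated correlation), and at -0.5 without that library (adjusted p = 6.6e-12), where 2 fell.

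The largest rises with 4-OHT in GFP cells began from a handful of counts. KRT13 had 956 counts with 4-OHT and 6 with vehicle, a ratio of 70.7 (95% counting interval 32.4 to 193), and GATA4, a developmental transcription factor (chromosome 8, 11534428 to 11617511), 593 and 6 counts, a ratio of 43.9 (20 to 120). The ratio was 43.9 for MPPED1 (14.9 to 214), 40.2 for ATP4A, a gastric proton pump subunit (13.6 to 196), 38.6 for MAG, a myelin glycoprotein (13.1 to 188), and 20.2 for the hair keratin KRT35 (5.43 to 169). MPPED1 had 0 counts with vehicle once GFP vehicle replicate 2 was left out, as had KRT35 without replicate 1, so that their fitted log2 fold changes (9.3 and 7.54) are then no bound. CD22, a B cell lectin located near MAG on chromosome 19, rose from 0.288 ± 0.023 to 6.76 ± 0.177 CPM (log2 fold change 4.51 ± 0.21), and CYP24A1, the vitamin D 24-hydroxylase, by 3.96 ± 0.42. Falls were those of the small GTPase gene ARL4D (-1.9 ± 0.2), RASL10A (-1.8 ± 0.25) and LINC01671 (-1.69 ± 0.21). The cholesterol acyltransferase SOAT2 (-2.22 ± 0.41), WNT6 (-1.94 ± 0.34), ZDHHC1 (-1.66 ± 0.46), PSCA (-1.54 ± 0.28) and the crystallin CRYGS (-1.53 ± 0.38) also fell, but these 5 did not pass without GFP vehicle replicate 2 (adjusted p = 0.066 to 0.61). Their log2 fold changes were then -2.01, -1.51, -0.88, -1.11 and -0.88, and ZDHHC1 and CRYGS did not pass without any 1 of 9 libraries each.

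Among other lists in GFP cells, interferon-stimulated genes fell with 4-OHT. The share of all tested genes called in this comparison was 12.9%. Of 38, 0 rose and 11 fell (0 and 15 adjusted over the list alone), with OAS1 at -0.73 ± 0.1 and IRF1 at -0.55 ± 0.11. As a list they lay at -0.29 (adjusted p = 0.0012, and adjusted p = 0.06 with an estimated correlation). With GFP vehicle replicate 2 left out 1 fell, and the list lay at -0.26 (adjusted p = 3.4e-07). Of 28 ER cofactor genes, 5 rose and 1 fell (8 and 2 adjusted over the list alone), with the progesterone receptor gene PGR at 1.69 ± 0.19 and RARA at 0.63 ± 0.13. Together the genes lay at 0.34 (adjusted p = 0.0063, and adjusted p = 0.38 with an estimated correlation) and at 0.21 without GFP vehicle replicate 2, where 2 rose and 0 fell. Of 28 cholesterol genes, 1 rose and 3 fell (5 and 6 adjusted over the list alone), with MSMO1 at 0.55 ± 0.14 and PMVK at -0.71 ± 0.19. Their mean log2 fold change was 0.01, their difference from other genes -0.02 and the direction of the test upward (adjusted p = 0.99), and 0 were called without that library.

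The ribosomal protein list lay at -0.64 with 4-OHT in GFP cells (adjusted p = 6.7e-13, but adjusted p = 0.65 with an estimated correlation), with 0 of 51 higher and 22 lower (0 and 47 adjusted over the list alone), RPS28 at -0.97 ± 0.23 and RPS19 at -0.93 ± 0.25. The respiratory chain list lay at -0.46 (adjusted p = 1.6e-06, but adjusted p = 0.65 with an estimated correlation), with 0 of 36 higher and 6 lower (1 and 28 adjusted over the list alone), NDUFA4 at -0.64 ± 0.16 and COX7A2 at -0.71 ± 0.18. Without GFP vehicle replicate 2 they lay at -0.24 and -0.16 with 0 genes called, and without GFP vehicle replicate 1 at -1.04 and -0.78. With the trend taken out they lay at -0.33 and -0.21, on 4-OHT replicates 1 and 2 alone at -0.39 and -0.28, and on replicates 3 and 4 alone at -0.91 and -0.64. The MHC list lay at -0.24 (adjusted p = 0.047, and adjusted p = 0.65 with an estimated correlation), with 0 of 18 higher and 4 lower (0 and 6 adjusted over the list alone), PSMB9 at -0.84 ± 0.21 and HLA-E at -0.44 ± 0.12. It lay at -0.08 without GFP vehicle replicate 2 (adjusted p = 0.22), with 0 called, and -0.45 without GFP vehicle replicate 1, and of the 12 left-out libraries only that replicate 1 and EZH2 4-OHT replicates 2, 3 and 4 left its call standing. Replication-dependent histone genes lay at -0.35 (adjusted p = 0.043, and adjusted p = 0.33 with an estimated correlation), with 0 of 18 higher and 2 lower (0 and 4 adjusted over the list alone), HIST1H1C at -0.63 ± 0.17 and HIST1H2AE at -0.75 ± 0.22. That list lay at -0.25 without GFP vehicle replicate 2 (adjusted p = 0.011), with 0 called. With the trend taken out it lay at 0.03 (adjusted p = 0.81), and its call was lost without GFP vehicle replicate 1.

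The test called 1867 genes for 4-OHT in GFP cells, 773 higher and 1094 lower, and 189 without GFP vehicle replicate 2 (143 higher and 46 lower), of which 183 were among the 1867, all with the same sign. Each of the 12 left-out libraries moved the count by over 1.5 times. It was 8111 without GFP vehicle replicate 1, 813, 5414, 320 and 312 without GFP 4-OHT replicates 1 to 4, 537, 846, 491 and 516 without EZH2 4-OHT replicates 1 to 4, and 471 without EZH2 vehicle replicate 1 or 2. On 4-OHT replicates 1 and 2 alone it was 71, on replicates 3 and 4 alone 4199, on the libraries of the comparison alone 78, and with DESeq2 4803.

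In EZH2 cells, 4-OHT raised estrogen-induced genes as well. GREB1 rose from 89.6 ± 0.417 CPM (SD, n = 2) to 211 ± 6.16 CPM (n = 4), a log2 fold change of 1.24 ± 0.2 (adjusted p = 0.0042). Of 34 estrogen-induced genes, 22 rose and 0 fell (25 and 0 adjusted over the list alone), among them RAPGEFL1 (2.69 ± 0.11), STC2 (1.68 ± 0.08), ADORA1 (2.76 ± 0.16) and the potassium channel gene KCNK5 (1.55 ± 0.09). The listed genes lay at 1.14 (adjusted p = 2.8e-119, and adjusted p = 5.7e-07 with an estimated correlation). All 15 estrogen-repressed genes were negative, 0 rose and 3 fell (0 and 11 adjusted over the list alone), namely BMF (-0.99 ± 0.09), CYP1A1 (-0.56 ± 0.11) and the lipase gene LIPH (-0.75 ± 0.15). That list lay at -0.51 (adjusted p = 7.4e-14, and adjusted p = 0.00039 with an estimated correlation), and 7 fell without GFP vehicle replicate 2. Of 28 cholesterol genes, 0 were called (0 adjusted over the list alone), with PCSK9 at -0.74 ± 0.25 and DHCR7 at 0.32 ± 0.11. The list lay at 0.02 (adjusted p = 0.47). GREB1's call ended without EZH2 vehicle replicate 1 (1.23, adjusted p = 0.1) or 2 (1.24, adjusted p = 0.097), and on 4-OHT replicates 1 and 2 (1.22, adjusted p = 0.084) or 3 and 4 (1.25, adjusted p = 0.064) alone.

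The largest 4-OHT rises in EZH2 cells again began from few or 0 counts. KRT35 had 0 counts with vehicle and 106 with 4-OHT, at least 16.4-fold higher against a floor of 3 counts over the group. GATA4 had 1 and 391 counts, a ratio of 181 (95% counting interval 32.4 to 7190), and PGLYRP2, a peptidoglycan recognition protein, 5 and 722, a ratio of 67 (28.6 to 207). The ratio was 50.9 for ATP4A (17.3 to 248), 48.3 for MAG (13.2 to 401), 33.3 for MPPED1 (12.9 to 123) and 26.3 for LINC01016 (8.85 to 129). MAG had 0 counts with vehicle without EZH2 vehicle replicate 1 and MPPED1 without replicate 2, and their fitted log2 fold changes (8.58 and 9.05) are then no bound. KRT13 rose from 0.409 ± 0.38 to 14.1 ± 1.86 CPM (log2 fold change 5.08 ± 0.34). Falls were those of ARL4D (-1.65 ± 0.17), the dopamine receptor DRD1 (-1.62 ± 0.37), the xenobiotic enzyme CYP1A2 (-1.44 ± 0.19), LINC01671 (-1.26 ± 0.18) and FHL1, a LIM protein (-1.25 ± 0.17). FBN2, a fibrillin (-1.08 ± 0.2), the epidermal factor GRHL3 (-1.07 ± 0.16) and TSPAN5 (-1.02 ± 0.19) also fell. LINC01671, FHL1, FBN2, GRHL3 and TSPAN5 did not pass without EZH2 vehicle replicate 1 (adjusted p = 0.052 to 0.29). Nor did FBN2 and TSPAN5 without EZH2 vehicle replicate 2 (adjusted p = 0.088 and 0.066), FBN2 without EZH2 4-OHT replicate 1 (adjusted p = 0.051), and DRD1 without any 1 of 10 libraries (adjusted p up to 0.43).

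Interferon-stimulated genes lay at -0.19 with 4-OHT in EZH2 cells (adjusted p = 2.6e-05, and adjusted p = 0.011 with an estimated correlation), with 29 of 38 negative and 0 called (0 higher and 4 lower adjusted over the list alone), HERC6 at -0.38 ± 0.1 and IRF1 at -0.4 ± 0.11. DNA replication genes lay at 0.14 (adjusted p = 0.00084, and adjusted p = 0.1 with an estimated correlation), with 28 of 33 positive and 0 called (0 adjusted over the list alone), MCM3 at 0.28 ± 0.08 and MCM6 at 0.27 ± 0.08. Basal and mesenchymal genes lay at -0.26 (adjusted p = 0.0046, and adjusted p = 0.26 with an estimated correlation), with 0 of 17 called (0 adjusted over the list alone), ANXA1 at -0.84 ± 0.25 and the caveolin gene CAV1 at -0.41 ± 0.13. They lay at -0.15 without EZH2 vehicle replicate 1. Of 29 immediate early genes, 2 rose and 1 fell (3 and 1 adjusted over the list alone), namely IER3 (1.21 ± 0.15), MYC (0.51 ± 0.09) and KLF4 (-0.59 ± 0.12). As a list they lay at 0.19 (adjusted p = 0.0046, and adjusted p = 0.24 with an estimated correlation) and at 0.15 with the trend taken out (adjusted p = 0.09). Developmental genes lay at 0.32 (adjusted p = 0.033, and adjusted p = 0.26 with an estimated correlation) through GATA4, the only 1 of 19 called (1 adjusted over the list alone), with WNT6 at -0.92 ± 0.32. Their call was lost with the trend taken out (adjusted p = 0.74) and without EZH2 4-OHT replicate 1 or EZH2 vehicle replicate 2. Ribosomal protein genes lay at 0.18 (adjusted p = 0.0022, and adjusted p = 0.67 with an estimated correlation), with 0 of 51 called (0 adjusted over the list alone), RPS28 at 0.35 ± 0.24 and RPL38 at 0.3 ± 0.21, and at 0.09 with the trend taken out (adjusted p = 0.051).

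Smaller groups of called genes lay in lists that did not pass in EZH2 cells, where 1.8% of all tested genes were called with 4-OHT. Of 25 growth factor receptor and adaptor genes, 3 rose and 1 fell (3 and 2 adjusted over the list alone), with the receptor RET at 1.21 ± 0.13 and TGFA at -0.73 ± 0.15 (list -0.05, adjusted p = 0.47). Of 28 ER cofactor genes, RARA (0.87 ± 0.13), GREB1 and PGR (0.98 ± 0.18) rose and 0 fell (3 and 2 adjusted over the list alone). Together the genes lay at 0.08 (adjusted p = 0.2). Of 20 AhR and xenobiotic genes, UGT2B15 rose (1.56 ± 0.23) and CYP1A2 and CYP1A1 fell (2 and 4 adjusted over the list alone). The listed genes lay at -0.07 (adjusted p = 0.18). Without GFP vehicle replicate 2, 4 AhR and 2 growth factor genes fell, as did 2 interferon-stimulated and 2 basal genes.

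The test called 260 genes for 4-OHT in EZH2 cells, 188 higher and 72 lower, and DESeq2 408. With the trend taken out, 468 were higher and 399 lower. The count moved by over 1.5 times without EZH2 vehicle replicate 1 or 2 (78 and 91), EZH2 4-OHT replicate 1, 3 or 4 (163, 169 and 166) and GFP vehicle replicate 1 or 2 (422 and 423, the latter with all 260 kept), was 80 and 113 on 4-OHT replicates 1 and 2 or 3 and 4 alone, and 1358 on the libraries of the comparison alone.

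**Figure D3:**
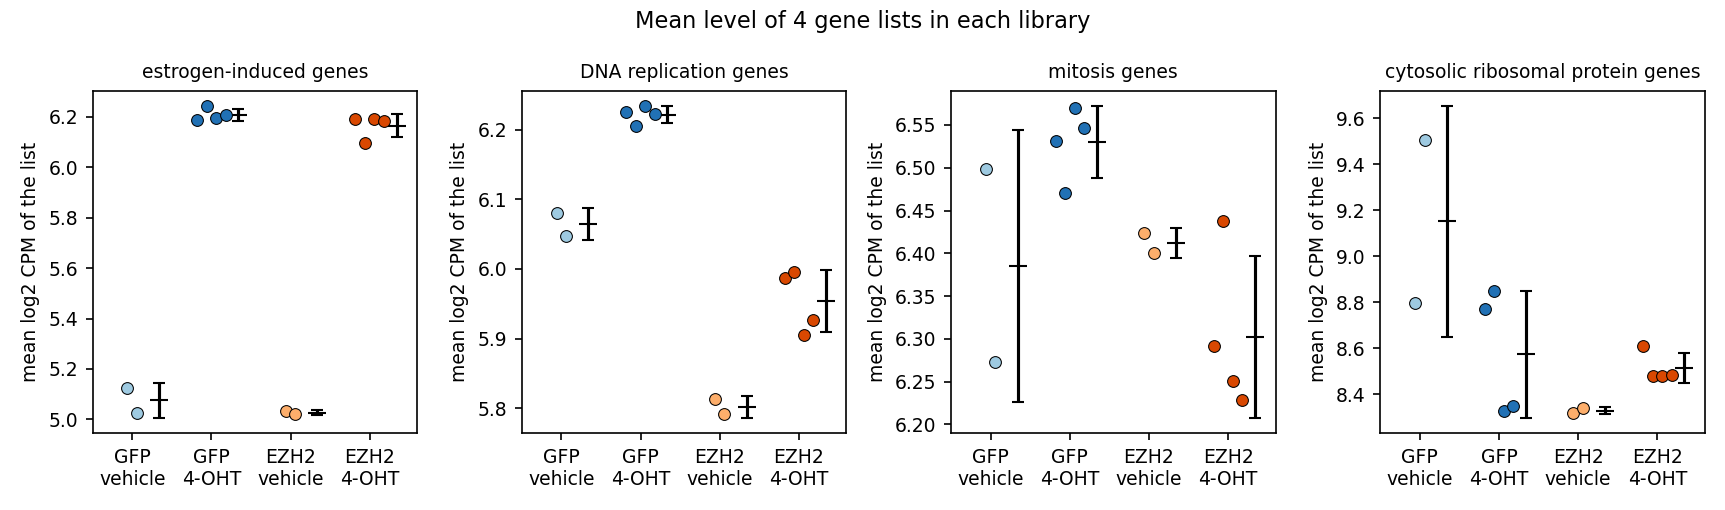
Mean log2 CPM of the members of 4 gene lists (y axes, which do not start at 0) in each library by group (x axes), with 1 point per library and a bar for mean ± SD of the group. Estrogen-induced genes lie higher in all 8 4-OHT libraries than in all 4 vehicle libraries, DNA replication genes lie lower in the 4 EZH2 4-OHT libraries than in the 4 GFP 4-OHT libraries, and ribosomal protein genes are highest in GFP vehicle replicate 2.

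The interaction asks whether the 4-OHT effect differed between EZH2 and GFP cells, and edgeR called 0 genes for it. At an unadjusted p below 0.05 there were 4625 genes, and 603 without GFP vehicle replicate 2, where 0 were called as well, and DESeq2 and limma-voom also called 0 genes (4942 and 4670 at an unadjusted p below 0.05). GREB1 had an interaction of -0.64 ± 0.26 (adjusted p = 0.15), and -0.31 without GFP vehicle replicate 2 (adjusted p = 0.68). ESR1 had -0.42 ± 0.2 (adjusted p = 0.16) and EZH2 -0.24 ± 0.1 (adjusted p = 0.15), and without that library -0.18 and -0.23. Without GFP vehicle replicate 1, which leaves replicate 2 as the only GFP vehicle library, 7203 genes passed and GREB1 stood at -1.05 (adjusted p = 0.0022). At the preset correlation 2 lists passed, and neither did with an estimated correlation (adjusted p = 0.68 for each). Ribosomal protein genes lay at 0.82 (adjusted p = 1.1e-17), with all 51 positive and 0 called (46 higher adjusted over the list alone), and respiratory chain genes at 0.57 (adjusted p = 3.1e-08), with 34 of 36 positive and 0 called (21 higher adjusted over the list alone). They lay at 0.42 and 0.27 without GFP vehicle replicate 2 and at 0.42 and 0.25 with the trend taken out. Respiratory chain genes lay at 0.88 without GFP vehicle replicate 1. The estrogen-induced list lay at 0.04 (adjusted p = 0.54) and the estrogen-repressed list at 0.02, with a mean of -0.01 (adjusted p = 0.99).

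The 4-OHT effects in the 2 cell populations shared 152 genes that rose (10 by chance) and 39 that fell (5.44 by chance), with 0 called in opposite directions. Over all 14477 genes their log2 fold changes had a Pearson r of 0.2 and a Spearman rho of -0.16 across genes, and without GFP vehicle replicate 2 these were 0.42 and 0.08. The Pearson r was 0.02 without GFP vehicle replicate 1 and 0.48 with the trend taken out. Of the 1936 genes called in either population, 62.6% had the same sign in both, and 98.4% of 444 without GFP vehicle replicate 2.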

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

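Of the tests in this part, thinning the counts was chosen before its result was seen, while those of the GC and length trend, the label, the cell population, the other splits of the libraries, the left-out library and the estimated correlation were chosen or worded only after results had been seen.

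GFP vehicle replicate 2 stood apart from the other libraries, with the SD over genes of its log2 difference from replicate 1 at 0.636, against at most 0.454 for any other pair of replicates. Depth as the whole cause is argued against, since with every library thinned to the lowest total the SD was 0.634 (highest other pair 0.459). A GC and length trend as the whole cause is argued against too, since the SD was 0.451 with the trend taken out (highest other pair 0.333), although the drop from 0.636 is consistent with the trend as a part of it. A wrong label is argued against, since the 188 genes raised by 4-OHT in EZH2 cells had a mean log2 CPM of 3.44 in this library, near the 3.4 of replicate 1 and below the lowest GFP 4-OHT library (4.63), and EZH2 stood at 90.9 CPM against at least 575 in the EZH2 libraries. RNA quality or another difference between cultures or preparations stays open, the labels give no batch, and no biological explanation was tested.

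DNA replication and mitosis genes were lower in EZH2 cells under 4-OHT, at -0.28 and -0.24 (with an estimated correlation adjusted p = 0.0016 for DNA replication, but 0.057 for mitosis, which did not pass). A GC and length trend as the whole cause is argued against, since with the trend taken out they lay at -0.27 (adjusted p = 3.1e-22) and -0.23 (adjusted p = 2.1e-15) at the preset correlation. Chance assignment of the 8 libraries to groups is argued against for DNA replication, since only 1 of the 35 splits, the real one, gave a difference as large (0.28 against a highest other of 0.17). For mitosis the real split was also the only one, but by a narrow margin (0.241 against 0.213). Chance is not excluded for either list. This is the smallest share that 35 splits can give, without allowance for the choice of these 2 from 24 lists after their falls were seen. For DNA replication, a difference between the populations apart from the construct cannot be told apart from an effect of EZH2, because each construct is carried by its own cells, and the vehicle libraries, at -0.32, share that design. Mitosis genes lay at -0.04 with vehicle (median 0.02, 15 of 30 positive, adjusted p = 0.67), at -0.12 without GFP vehicle replicate 2 (adjusted p = 0.085) and at -0.16 with the trend taken out (adjusted p = 0.0033), and an effect of EZH2 itself stays open.

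At the preset correlation, the 4-OHT effect on ribosomal protein and respiratory chain genes differed between EZH2 and GFP cells, at 0.82 (adjusted p = 1.1e-17) and 0.57 (adjusted p = 3.1e-08) in the test of the difference itself, but with the correlation estimated from the residuals neither list passed (adjusted p = 0.68 for each). Members that vary together between libraries are thus a candidate explanation for the small p-values, though that form of the test also has fewer degrees of freedom. With the GC and length trend taken out the differences were 0.42 and 0.25. Whether GFP vehicle replicate 2 alone makes them cannot be told apart, since without it they were 0.42 and 0.27, but 1 GFP vehicle library remained, and its list means (8.797 and 7.367) lay within those of the GFP 4-OHT libraries (8.326 to 8.848 and 7.064 to 7.404). What makes these transcripts vary together (RNA quality, preparation or growth state of the cells) stays open.

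For EZH2 against GFP with 4-OHT, only 1 of the 35 splits, the real one, gave as many as 150 genes (highest other 0). Chance assignment of the 8 libraries is thus argued against for the number of genes. It is not excluded, since this is the smallest share that 35 splits can give and every other split mixes the constructs within its groups. For the number of gene lists chance assignment stays open, since 4 of the 35 splits gave as many as the real 7 (highest other 7).

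In groups of 4 libraries, 9 single values stood apart among 162 groups tested, and chance alone sets a value apart in about 1 in 20 groups. Among GFP 4-OHT libraries, in mean log2 CPM, ATP4A was 2.05 in replicate 2 (nearest other 1.63), FHL1 was 2.06 in replicate 4 (nearest 2.21), and unfolded protein and stress response genes stood at 6.53 in replicate 4 (nearest 6.51). Among EZH2 4-OHT libraries, NECAB1 was 0.651 in replicate 1 (nearest 0.84), AhR genes stood at 5.11 (nearest 5.24) and ribosomal protein genes at 8.61 (nearest 8.48) in replicate 1. In EZH2 4-OHT replicate 2, estrogen-induced genes stood at 6.1 (nearest 6.18), NF-kB genes at 2.62 (nearest 2.72) and ER cofactor genes at 7 (nearest 7.03).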

How the results depend on the processing

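The offset on GC content and length, with and without GFP vehicle replicate 2, the thinning of counts, the PRC2 list without EZH2 and the list tests within pairs of 4-OHT replicates were chosen after the data were seen, and the other alternatives before. Except where the design of an alternative is named, the cause of a change was not tested. For lists, the offset cannot be told apart from the form of the test, which changed with it. Nor can the estimated correlation be told apart from the fewer degrees of freedom used with it.

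RLE and upper-quartile factors, no filter, the strict filter, limma-voom, the series table and thinning left the gene counts of all 5 comparisons within 1.5 times. For the 4 comparisons of groups, in the order EZH2 against GFP with vehicle (4944), with 4-OHT (150), 4-OHT in GFP cells (1867) and in EZH2 cells (260), the test against a 1.2-fold minimum gave 16, 48, 229 and 151 genes. The replicate block gave 2479, 52, 138 and 127. 4-OHT replicates 1 and 2 alone gave 5, 1, 71 and 80, and replicates 3 and 4 alone 4, 2, 4199 and 113, with fewer libraries. DESeq2 gave 364 for EZH2 against GFP with 4-OHT, 4803 for 4-OHT in GFP cells and 408 in EZH2 cells. The libraries of the comparison alone gave 0 by edgeR (3097 at an unadjusted p under 0.05) for EZH2 against GFP with vehicle, with 2 residual degrees of freedom, 78 for 4-OHT in GFP cells and 1358 in EZH2 cells. The offset gave 839 for EZH2 against GFP with 4-OHT and 867 for 4-OHT in EZH2 cells. For EZH2 against GFP with vehicle it gave 1251 higher and 2126 lower (2358 and 2586 without the offset). For 4-OHT in GFP cells it gave 1151 higher and 1622 lower (773 and 1094 without it). The offset without GFP vehicle replicate 2 gave 250, 1500, 714 and 1436.

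Leaving out 1 library at a time gave 7 to 8395, 58 to 325, 189 to 8111 and 78 to 423 genes in the same order, and 0 to 7203 for the interaction. The lowest came without EZH2 vehicle replicate 1 or 2, EZH2 4-OHT replicate 4, GFP vehicle replicate 2 and EZH2 vehicle replicate 1, and the highest without GFP vehicle replicate 1, 2, 1 and 2 and, for the interaction, 1. Where this left a group with 1 library, that library was assumed to vary like the other groups.

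EZH2 kept its direction and call under all alternatives, except that on the vehicle libraries alone its difference with vehicle was 2.87 (adjusted p = 0.11). GREB1 with vehicle (0.58) passed with upper-quartile factors (0.6), no filter (0.6), DESeq2 (0.57) and limma-voom (0.62), as well as without GFP vehicle replicate 1 (0.99, adjusted p = 0.00082) and GFP 4-OHT replicate 2 (0.57, adjusted p = 0.048). Its lowest value with 1 library left out was 0.26, without GFP vehicle replicate 2, and with the offset it was 0.28, or 0.02 without that library as well. The rise of GREB1 with 4-OHT in EZH2 cells (1.24) did not pass on 4-OHT replicates 1 and 2 alone (1.22) or 3 and 4 alone (1.25), and ran from 1.22 to 1.25 with 1 library left out. Its interaction (-0.64) ran from -1.05 without GFP vehicle replicate 1 to -0.31 without replicate 2.

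The number of gene lists past the threshold, 6, 7, 8 and 8 in the same order and 2 for the interaction, fell to 0, 1, 2, 3 and 0 with an estimated correlation. On 4-OHT replicates 3 and 4 alone it was 3 for EZH2 against GFP with 4-OHT. With fry it was 17 for EZH2 against GFP with vehicle and 0 for the interaction, and with the offset without GFP vehicle replicate 2 it was 4 for the interaction. With 1 library left out the interaction had 2 to 4 lists, the 4 without EZH2 4-OHT replicate 2. The Pearson r between the effects of EZH2 with and without 4-OHT (0.38) was 0.7 on 4-OHT replicates 1 and 2 alone and 0.14 to 0.53 with 1 library left out (GFP 4-OHT replicates 2 and 3). That between the 4-OHT effects in the 2 populations (0.2) was 0.37 on replicates 1 and 2 alone, 0.48 with the offset, and 0.02 to 0.42 with 1 library left out (GFP vehicle replicates 1 and 2).

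Signs of values past the threshold with all libraries or in the alternative changed in these cases. With the offset, for EZH2 against GFP with vehicle, replication-dependent histone genes lay at 0.14, SUSD3 at 0.01, IRX3 at 0.03, HIST1H1C at 0.01, and ESR1 at -0.04, or -0.09 without GFP vehicle replicate 2 as well. For 4-OHT in GFP cells, histone genes lay at 0.03 with the offset. On 4-OHT replicates 3 and 4 alone, for EZH2 against GFP with 4-OHT, ribosomal protein genes lay at 0.14 (-0.09 with all libraries) and respiratory chain genes at 0.01 (-0.12). Values that passed in neither also changed sign. Over all alternatives, lists stayed on their side of the threshold in 448 cases for 4-OHT in EZH2 cells (7 with another sign), lost the call in 13 and gained it in 14. For 4-OHT in GFP cells these were 445 (19), 21 and 8, for EZH2 against GFP with vehicle 452 (13), 12 and 10, and with 4-OHT 438 (21), 25 and 10. Among named genes and list members, calls were lost in 854 cases for EZH2 against GFP with vehicle, 173 with 4-OHT, 701 for 4-OHT in GFP cells and 149 in EZH2 cells. Genes that an alternative's filter removed have no value there.

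Depth changed little in these counts. Thinned to the lowest total, the 4 comparisons gave 4892, 113, 2210 and 232 genes among 14106 tested. It limits folds from low counts, as for KRT35, which had 0 counts with vehicle in EZH2 cells.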

Other observations

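Several lists outside the report's main account held called genes in the comparison of EZH2 with GFP cells under vehicle. None of them passed as a list by camera with all libraries. Of all genes tested, 34.2% were called there, the share against which the counts below are to be read. With fry, luminal, interferon-stimulated, ER cofactor, AhR and NF-kB genes passed (adjusted p = 0.0038 to 0.023), while mitosis and basal genes did not. With GFP vehicle replicate 2 left out, 0 members of the lists in this part and the next were called. Interferon-stimulated genes passed at -0.2 without GFP vehicle replicate 2 (adjusted p = 0.0047). With the GC and length trend taken out, these passed at -0.22 (adjusted p = 0.0029), mitosis genes at -0.16 (adjusted p = 0.0033), estrogen-repressed genes at 0.21 (adjusted p = 0.024) and replication-dependent histone genes, at -0.43 with all libraries, at 0.14 (adjusted p = 0.024). All members named here as changed under vehicle lost their call without GFP vehicle replicate 2 (adjusted p = 0.093 to 0.38). Of 24 luminal genes, 3 rose and 11 fell (4 and 12 adjusted over the list alone), with the keratin KRT18 at -0.8 ± 0.2 and ELF3 at -0.43 ± 0.11 (list -0.28, adjusted p = 0.094). Of 38 interferon-stimulated genes, 1 rose and 14 fell (1 and 14 adjusted over the list alone), with OASL at -0.9 ± 0.14 and IFI35 at -0.99 ± 0.23 (list -0.23, adjusted p = 0.094). Of 28 ER cofactor genes, 10 rose and 2 fell (11 and 2 adjusted over the list alone), with the acetyltransferase gene EP300 at 1.04 ± 0.25 and NCOA3 at 0.78 ± 0.21 (list 0.27, adjusted p = 0.1). Of 20 AhR and xenobiotic genes, 8 rose and 2 fell (10 and 4 adjusted over the list alone), with CYP1A1 at 0.51 ± 0.13 and CYP1A2 at 0.88 ± 0.22 (list 0.33, adjusted p = 0.1). Of 20 NF-kB genes, 0 rose and 6 fell (0 and 6 adjusted over the list alone), with RELB at -0.96 ± 0.21 and the chemokine CCL5 at -1.07 ± 0.24 (list -0.26, adjusted p = 0.094). Of 30 mitosis genes, 1 rose and 8 fell (1 and 8 adjusted over the list alone), with AURKB at -0.83 ± 0.17 and PTTG1 at -0.95 ± 0.21 (list -0.04 but median 0.02, adjusted p = 0.67, and -0.12 without GFP vehicle replicate 2). Of 17 basal and mesenchymal genes, 5 rose and 2 fell (6 and 2 adjusted over the list alone), with LAMC2 at 1.34 ± 0.34 and SNAI1 at -1.38 ± 0.27 (list 0.13, adjusted p = 0.47).

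Other lists went both ways under vehicle. With fry, p53, unfolded protein, estrogen-repressed and histone genes passed (adjusted p = 0.016 to 0.049), and the others in this paragraph did not. Of 25 p53 targets, 5 rose and 9 fell (6 and 10 adjusted over the list alone), with AEN at -0.45 ± 0.1 and BAX at -0.91 ± 0.24 (list -0.06 but median 0.05, adjusted p = 0.65). Of 25 unfolded protein and stress response genes, 6 rose and 7 fell (6 and 8 adjusted over the list alone), with PPP1R15A at -0.69 ± 0.14 and PSAT1 at 0.72 ± 0.16 (list -0.1, adjusted p = 0.46). Of 28 cholesterol genes, 5 rose and 6 fell (5 and 6 adjusted over the list alone), with TM7SF2 at -0.86 ± 0.22 and the desaturase SCD at 0.56 ± 0.15 (list -0.02 but mean 0.02, adjusted p = 0.99). Of 15 estrogen-repressed genes, 5 rose and 3 fell (6 and 4 adjusted over the list alone), with BCAS1 at 0.76 ± 0.12 and YPEL3 at -0.74 ± 0.21 (list 0.09, adjusted p = 0.46). Of 25 growth factor receptor and adaptor genes, 4 rose and 2 fell (3 and 0 adjusted over the list alone), with FGFR2 at 1.21 ± 0.19 and GRB7 at -0.62 ± 0.2 (list 0.03, adjusted p = 0.62). Of 27 hypoxia and glycolysis genes, 1 rose and 2 fell (1 and 0 adjusted over the list alone), with EGLN3 at 0.66 ± 0.16 (list 0.05, adjusted p = 0.62), and of 18 histone genes 1 rose and 3 fell (1 and 3 adjusted over the list alone; list -0.43, adjusted p = 0.19). Developmental genes held 1 rise and 1 fall among 19 (0 adjusted over the list alone; list -0.2, adjusted p = 0.75), and 0 of 5 markers of fibroblasts, endothelium and leukocytes were called (0 adjusted over the list alone; list -0.25, adjusted p = 0.7). With GFP vehicle replicate 2 left out the list values were -0.18 for luminal, 0.15 for ER cofactor, 0.22 for AhR, -0.18 for NF-kB, 0.01 for basal, -0.07 for p53, -0.04 for unfolded protein, -0.01 for cholesterol, 0.12 for estrogen-repressed, -0.04 for growth factor, 0.01 for hypoxia, -0.34 for histone and -0.21 for developmental genes and 0.12 for the 5 markers (adjusted p = 0.056 to 1).

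With 4-OHT in GFP cells, genes of several further lists moved, and again none of these lists passed by camera with all libraries. The share of all tested genes called in this comparison was 12.9%. DNA replication genes passed at 0.11 without GFP vehicle replicate 2 (adjusted p = 0.0034) and at 0.13 with the trend taken out (adjusted p = 0.0029), as did immediate early genes (0.23) and developmental genes (0.28) with the trend taken out (adjusted p = 0.038 for each). Basal and mesenchymal genes, with 0 of 17 higher and 1 lower (0 and 3 adjusted over the list alone), lay at -0.15 (adjusted p = 0.46) and passed at -0.22 without that library (adjusted p = 0.011). The glucose transporter SLC2A1 rose by 1.02 ± 0.09 and NDRG1 stood at -0.76 ± 0.09 among 27 hypoxia and glycolysis genes, of which 2 rose and 5 fell (5 and 8 adjusted over the list alone; list -0.06, adjusted p = 0.92). In EZH2 cells the same 2 genes stood at 1 ± 0.09 and -0.73 ± 0.09. Of 29 immediate early genes, 4 rose and 2 fell (5 and 3 adjusted over the list alone), with EGR3 at 2.44 ± 0.31 and IER3 at 0.86 ± 0.14 (list 0.1, adjusted p = 0.56). Of 20 AhR and xenobiotic genes, 2 rose and 4 fell (5 and 4 adjusted over the list alone), with UGT2B15 at 1.51 ± 0.22 and HMOX1 at -0.72 ± 0.11 (list 0.16, adjusted p = 0.83). Of 25 growth factor receptor and adaptor genes, 3 rose and 3 fell (6 and 5 adjusted over the list alone), with RET at 1.6 ± 0.13 and IRS2 at 0.92 ± 0.15 (list 0.07, adjusted p = 0.47). Of 25 p53 targets, 2 rose and 7 fell (3 and 8 adjusted over the list alone), with CDKN1A at -0.61 ± 0.12 and GDF15 at 0.71 ± 0.17 (list -0.06, adjusted p = 0.62). Of 24 luminal genes, 4 rose and 3 fell (6 and 8 adjusted over the list alone), with the pioneer factor FOXA1 at 0.67 ± 0.14 and GATA3 at -0.36 ± 0.08 (list -0.13, adjusted p = 0.56). Of 33 DNA replication genes, 5 rose and 0 fell (9 and 0 adjusted over the list alone), with MCM10 at 0.68 ± 0.16 and E2F8 at 0.63 ± 0.15 (list 0.11, adjusted p = 0.15). Of 25 unfolded protein and stress response genes, 5 rose and 4 fell (6 and 7 adjusted over the list alone; list -0.04, adjusted p = 0.8), of 20 NF-kB genes 1 rose and 2 fell (1 and 3 adjusted over the list alone; list -0.11, adjusted p = 0.47), and of 18 genes described as EZH2-repressed 3 rose and 2 fell (4 and 3 adjusted over the list alone; list 0.12, adjusted p = 0.62). Of 19 developmental genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone; list 0.11, adjusted p = 0.45). With GFP vehicle replicate 2 left out, 1 hypoxia gene rose and 2 fell, 2 immediate early genes rose and 1 fell, 1 AhR gene rose and 2 fell, and 2 growth factor genes rose. In the p53, luminal, EZH2-repressed and developmental lists 1 gene each rose, and 0 were called in the DNA replication, unfolded protein, NF-kB and basal lists. The list values then were -0.1 for hypoxia, 0.09 for immediate early, 0.05 for AhR, 0.01 for growth factor, -0.07 for p53, -0.02 for luminal, 0.02 for unfolded protein, -0.02 for NF-kB, 0.07 for EZH2-repressed and 0.1 for developmental genes (adjusted p = 0.44 to 0.94). SLC2A1, NDRG1, EGR3, IER3, UGT2B15, HMOX1, RET, IRS2 and GDF15 also passed in GFP cells without GFP vehicle replicate 2 (adjusted p up to 0.045), while CDKN1A, FOXA1, GATA3, MCM10 and E2F8 did not (adjusted p = 0.1 to 0.36).

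List calls in this paragraph are at the preset correlation of 0.01. For EZH2 against GFP with 4-OHT the residuals gave 0.886 for ribosomal protein and 0.632 for respiratory chain genes. Other alternatives also gave calls to lists that did not pass with all libraries. For EZH2 against GFP with 4-OHT these were growth factor receptor and adaptor genes with the trend taken out (-0.13, adjusted p = 0.039) and without GFP 4-OHT replicate 1 (-0.12, adjusted p = 0.045). NF-kB genes passed on 4-OHT replicates 1 and 2 alone (-0.22, adjusted p = 0.044) and without GFP 4-OHT replicate 3 (-0.17, adjusted p = 0.042), and luminal genes with the trend and GFP vehicle replicate 2 taken out (-0.06, adjusted p = 0.039). Ribosomal protein genes passed without GFP 4-OHT replicate 3 or 4 (-0.17 each) and EZH2 4-OHT replicate 1 (-0.12), beside the pairs given in the report. For 4-OHT in EZH2 cells, mitosis genes passed on 4-OHT replicates 3 and 4 alone (-0.18, adjusted p = 0.00066), with the trend taken out (-0.09, adjusted p = 0.0072), without GFP vehicle replicate 1 or 2 (-0.11 each) and without EZH2 4-OHT replicate 2 (-0.16). Respiratory chain genes passed on replicates 1 and 2 alone (0.16, adjusted p = 0.013), with the replicate block (0.22), without GFP vehicle replicate 1 or 2 (0.11 each) and without EZH2 4-OHT replicate 4 (0.13). AhR genes passed on replicates 1 and 2 alone (-0.15, adjusted p = 0.023), and histone genes with the trend taken out (-0.17, adjusted p = 0.029). In the interaction, the MHC list passed with the trend taken out (0.37, adjusted p = 0.016) and on replicates 3 and 4 alone (0.47, adjusted p = 0.038). It also passed without EZH2 4-OHT replicate 1 or 2 (0.35 and 0.37), as did mitosis genes without EZH2 4-OHT replicate 2 (-0.25, adjusted p = 0.023). With the trend and GFP vehicle replicate 2 both taken out, mitosis genes passed in the interaction too (-0.06, adjusted p = 0.022), as did estrogen-induced genes for EZH2 against GFP with vehicle (-0.08, adjusted p = 0.026).

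One hypothesis, tested with a prediction set before its result was seen, was that chromosome segments gained or lost in a cell population lie behind differences between EZH2 and GFP cells, as they could in a line with an unstable genome. Neighbouring genes would then share fold changes under 4-OHT more than in a comparison within 1 population. Their rank correlation was 0.092, above the highest of 1000 permutations (0.028, permutation p = 0.001, the smallest they can give), but below the 0.178 of 4-OHT against vehicle in EZH2 cells, a difference of -0.086. In the 2 comparisons that include the GFP vehicle libraries it was 0.296 and 0.317. Medians of 492 windows of 30 genes correlated at 0.21 between the vehicle comparison (without GFP vehicle replicate 2) and the 4-OHT comparison. Both values argue against large segments as the main source, while the vehicle groups hold fewer libraries and trends on GC content also join neighbours, so single small segments remain open.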
